A study of Rattus norvegicus with 34 samples.

How the data were processed

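RNA was measured on Affymetrix rat expression arrays, 1 array per sample, for 34 samples. Of these, 18 came from NRK-52E cells, 8 from rat kidney and 8 from rat liver. The deposited values are log2 expression values per probe set that the authors obtained with GCRMA, per the submitters' processing notes, and the version and probe set definition are not given in the sources used here. GCRMA corrects for background, brings arrays to a common distribution and summarises the probes of each set. The value distributions were tested on the values themselves: arrays of 1 sample type shared nearly the same distribution, with a mean difference between the quantiles of array pairs of 0.038 among the cell arrays, 0.027 among the kidney arrays and 0.037 among the liver arrays, and of 0.104, 0.054 and 0.083 in the pair furthest apart. The mean difference was 0.346 between cells and kidney, 0.482 between cells and liver and 0.148 between kidney and liver. Values were therefore compared only within a sample type, and the organs were compared only through their treatment differences. Arrays have no read depth, and the number of arrays per group limits the precision.

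The table held 31099 probe sets. The 57 control probe sets were left out. Of the rest, 20826 carried 1 gene symbol in the array annotation, 436 carried several and 9780 carried none. For each of the 14217 named genes the probe set with the highest mean over the arrays of the fit was used. A probe set was tested if it lay above the median of its own array on at least as many arrays as the smallest group of the fit. This left 9042 genes in the cells, 9542 in kidney, 9361 in liver and 10116 in the joint fit of both organs.

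Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend). The test is two-sided and moderated, and its p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The 18 cell arrays were fitted together as 6 groups of 3 arrays, and monuron was compared with DMSO at each of the 3 times. The same fit gave the change of that difference between times and the change of the DMSO cells over time. Kidney and liver were fitted apart, with 4 arrays against 4 in each. A joint fit of the 16 tissue arrays tested whether the treatment difference itself differed between the organs. Each standard error (SE) is the moderated one of limma, and each SD is that of the arrays of a group. Overlaps between lists of called genes were tested with Fisher's exact test across genes, one-sided for each direction. Genes are not independent replicates, and the overlap p-values describe genes only.

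A set of 38 gene lists (pathways, transcription factor targets and cell type markers) was fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Of the 1331 list entries, 1136 were on the array. Each list with at least 5 measured members was tested with camera (limma), which compares the members with all other genes, at a preset inter-gene correlation of 0.01. Over the 5 main comparisons 163 list tests were made and adjusted together, and the 212 list tests of the remaining comparisons were adjusted together as a second family. In the main family 58 tests passed the threshold. With a correlation estimated from the data, 0 of the camera calls held, and 12 of the 163 tests had an unadjusted p below 0.05. fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes, called 41 of the 163 tests, and its mixed version, which asks for change in either direction, called 113. The counts called "adjusted over the list alone" were adjusted over the members of a list and not over all genes.

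The named genes follow a rule. For each main comparison they are the 8 genes with the largest positive and the 8 with the largest negative log2 change among genes past the threshold whose values did not overlap between the groups (placeholder symbols skipped), up to 4 members with the smallest adjusted p from each list, and a fixed panel of genes for xenobiotic metabolism, stress, the cell cycle and the clock. For the interactions, the overlaps and the DMSO time course they are the 5 genes with the smallest adjusted p in each direction. The text names part of them.

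The labels give treated and control samples the same replicate numbers and state no meaning for them. Whether the numbers pair the samples was checked with the correlation of the deviations from the group means across genes. At 6 h the correlations of the 3 same-numbered pairs of monuron and DMSO arrays were 0.491, 0.197 and 0.290, and at 72 h they were 0.205, 0.167 and 0.317. The highest correlations between unlike numbers were 0.301 at 6 h and 0.275 at 72 h, above part of these values. At each of these times 4 of 6 arrays correlated best with their own number. There the data give a hint that the numbers pair the samples, which the labels do not say. At 24 h the values were -0.116, -0.116 and 0.128, and there the numbers do not pair them. The fits behind the values in the text have no block at any time, as fixed before the data were examined, and the fits with the replicate number as a block are alternatives.

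The alternatives were arrays centred on their medians, quantile normalization within a fit, no filter or a filter at the 75th percentile, the mean of the probe sets of a gene, every probe set on its own, eBayes without trend or robust, array weights, an adjusted p threshold of 0.01, a minimum change of 2-fold, fits on the arrays of 1 time or on both organs, replicate blocks, and each array left out in turn. Fits without the 72 h arrays, or without the 72 h arrays of replicate 3, and fits with every value below the median of its array set to that median (limited differences), were added after the data had been seen. The procedure was tested on simulated data with the observed means and spreads and about 200 changed genes per size. Of genes changed 2-fold, 90.0% were recovered at 6 h, 92.4% at 24 h, 90.5% at 72 h, 92.0% in kidney and 86.4% in liver. Of genes changed 1.5-fold, 66.0%, 72.0%, 67.8%, 68.8% and 59.5% were recovered in the same order. False calls made up between 4.7% and 5.7% of the calls. A list of 55 genes shifted by 0.5 was called in each of the 5 simulated comparisons, and 0 other lists were called. The simulated genes varied independently of each other, so this cannot tell how often camera calls lists falsely among correlated genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and drew the plots.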

Results

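Transcript levels were measured in 34 rat samples labelled as exposed to monuron, a phenylurea herbicide, or to its vehicle. The cells were NRK-52E, an epithelial line from rat kidney with properties of the proximal tubule. They were exposed to monuron or to 0.1% DMSO for 6, 24 or 72 h, with 3 arrays for each compound and time. The rats were male, 7 to 9 weeks old and 190 to 240 g in weight, and received corn oil (5 ml/kg) alone or with monuron at 40 mg/kg on the first day and at 400 mg/kg on the following days. Kidney and liver were profiled, with 4 arrays labelled monuron and 4 labelled control in each organ. The labels do not say whether both organs came from the same 8 rats. The labels give 72 h for the tissue and the title of the series speaks of 72 h of exposure, while the protocol says that the rats were killed 72 h after the last dose. Whether the rat differences show exposure or recovery is therefore open. For the cells the protocol names another compound, chlorothalonil, and its concentration, while the sample labels say monuron. The identity of the compound on the cells is therefore in doubt and its concentration is not known, and the word monuron below follows the labels. All values are log2 expression, all changes are log2 differences of monuron minus control, and between arrays of a group Pearson's r across probe sets was 0.987 to 0.999. At 6, 24 and 72 h the arrays compared were 3 against 3, and in each organ 4 against 4. For each gene that a treatment comparison names as past the threshold, all arrays of 1 group lay on 1 side of all arrays of the other, which chance gives for 10% of genes with 3 arrays against 3. Some genes lay below the median of the arrays in 1 group, near the background, and there the size of a difference is uncertain. For these a limited difference is given as well, with every value below the median of its array set to that median, an alternative chosen after the data had been seen. The plot of called genes shows how many genes passed the threshold.

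**Figure D1:**
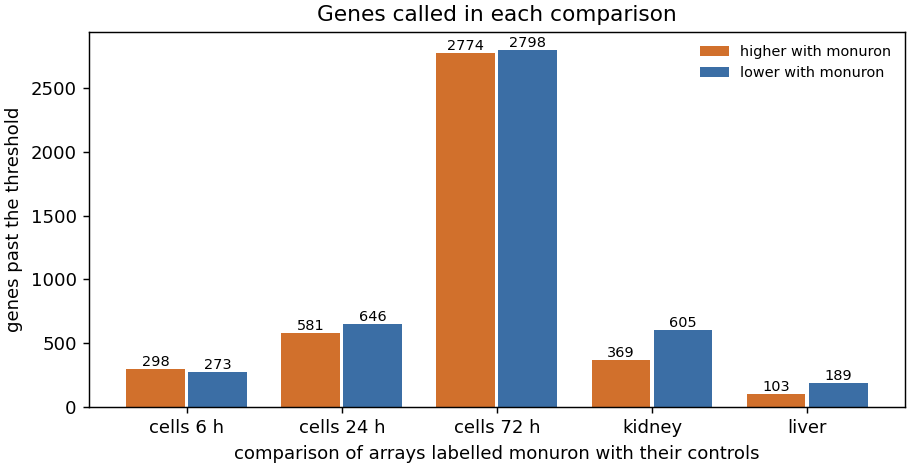
Genes past the threshold (vertical axis, number of genes) in each comparison of arrays labelled monuron with their controls (horizontal axis), higher in orange and lower in blue. The 72 h cells had 2774 higher and 2798 lower genes, far more than the 6 h cells with 298 and 273.

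Cells exposed to monuron for 6 h were compared with cells in DMSO. Part of the genes of the response to amino acid shortage, which the transcription factor ATF4 drives, were higher with monuron. Chac1, an enzyme that degrades glutathione, was higher by 3.25 (SE 0.64, n = 3 against 3, adjusted p = 0.0097; mean 9.69 ± 0.25 SD against 6.44 ± 0.26), Cars1, the cysteinyl-tRNA synthetase, by 1.46 (SE 0.27, adjusted p = 0.0067) and the transcription factor Cebpg by 0.77 (SE 0.12, adjusted p = 0.0022). Of the 40 measured members of the ATF4 list, 9 rose and 0 fell (13 and 0 adjusted over the list alone). Their median was 0.52 (camera adjusted p = 2.14e-09, and adjusted p = 0.6297 with an estimated correlation). Trib3 and Asns, further targets of ATF4, were higher by 1.73 (SE 0.91, adjusted p = 0.2710) and 0.53 (SE 0.51, adjusted p = 0.5782) without passing. Both passed without DMSO 72 h replicate 3 in the fit (adjusted p = 0.0017 and 0.0054). The 9 members of the list became 26 without that array, 5, 2 or 4 without monuron 6 h replicate 1, 2 or 3, and 4 or 5 without DMSO 6 h replicate 1 or 2. Other large increases were in Slc25a27, a mitochondrial carrier (2.18, SE 0.25, limited 1.62), in the nucleic acid binding gene Purg (2.15, SE 0.18, adjusted p = 1.63e-05) and in the zinc finger gene Zfp800 (1.83, SE 0.19).

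Part of the lipid synthesis genes were lower at 6 h. Tm7sf2, a sterol reductase, fell by 2.38 (SE 0.51, adjusted p = 0.0146), and Stard4, which moves cholesterol inside cells, fell by 1.20 (SE 0.26, adjusted p = 0.0146). The squalene synthase gene Fdft1 was at 9.26 ± 0.28 SD against 10.76 ± 0.03 (SE of the difference 0.33, adjusted p = 0.0155). Of 23 genes of cholesterol synthesis and uptake 10 fell and 0 rose (18 and 0 adjusted over the list alone). Their median was -1.35 (camera adjusted p = 5.78e-10, and adjusted p = 0.5157 with an estimated correlation). Of 19 genes of fatty acid synthesis 4 fell and 0 rose (8 and 0 adjusted over the list alone), among them the fatty acid synthase Fasn with -1.06 (SE 0.20, adjusted p = 0.0085). The median of that list was -0.45 (camera adjusted p = 2.35e-04, and adjusted p = 0.6297 with an estimated correlation). Genes of glycolysis and the hypoxia response were lower in 5 of 32 cases and higher in 0 (9 and 0 adjusted over the list alone), such as the oxygen sensor Egln1 with -0.53 (SE 0.09, adjusted p = 0.0038), with a list median of -0.24 (camera adjusted p = 2.29e-05, and adjusted p = 0.6297 with an estimated correlation). In the mitochondrial respiratory chain 7 of 55 genes fell and 0 rose (27 and 0 adjusted over the list alone), by a median of -0.17 (camera adjusted p = 1.11e-10, and adjusted p = 0.5157 with an estimated correlation). Without monuron 6 h replicate 2 the calls ended for Chac1 (adjusted p = 0.0553), Tm7sf2 (0.0822), Fdft1 (0.0867), Stard4 (0.0760) and Fasn (0.0559). Tm7sf2, Fdft1 and Stard4 were also not called without monuron 6 h replicate 3 (0.0681, 0.0594 and 0.0530), nor Tm7sf2 and Fdft1 without DMSO 6 h replicate 1 (0.0775 and 0.0591). The counts of list members depended on single arrays too. Without monuron 6 h replicate 1, 2 or 3 the 10 cholesterol genes became 3, 0 or 0, without DMSO 6 h replicate 1, 2 or 3 they became 1, 3 or 5, and without DMSO 72 h replicate 1 or 3 they became 18 or 19. The 4 fatty acid genes became 1, 0 or 2 without monuron 6 h replicate 1, 2 or 3, 1 without DMSO 6 h replicate 1 or 2, and 9 without DMSO 72 h replicate 1 or 3. The 5 glycolysis genes became 1 or 3 without monuron 6 h replicate 2 or 3, 3 without DMSO 6 h replicate 1, 2 or 3, and 10 or 12 without DMSO 72 h replicate 1 or 3. The 7 respiratory chain genes became 3, 0 or 0 without monuron 6 h replicate 1, 2 or 3, 0 without DMSO 6 h replicate 1, and 16 without DMSO 72 h replicate 3.

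At 6 h limma called 571 of 9042 genes, 298 higher and 273 lower, and 67 of them changed at least 2-fold. With the replicate number as a block, as the data hint at pairs at 6 h, 1030 genes were called. The list tests with this block were chosen after the data had been seen. In them the list of glutathione and glucuronosyl transferases lay lower (camera adjusted p = 0.0343), but it did not pass without the block (adjusted p = 0.0633, and adjusted p = 0.6297 with an estimated correlation). With arrays centred on their medians the split was 175 higher and 389 lower. The count fell to 378, 103 or 176 without monuron 6 h replicate 1, 2 or 3, to 162 or 300 without DMSO 6 h replicate 1 or 2, and was 926 or 1197 without DMSO 72 h replicate 1 or 3.

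After 24 h part of the genes for stress, xenobiotic metabolism and the clock were higher with monuron. Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, rose by 3.09 (SE 0.41, adjusted p = 3.74e-04; 6.47 ± 0.05 SD against 3.39 ± 0.40, n = 3 against 3). As the DMSO value lay below the array medians, the limited rise was 2.34 (adjusted p = 8.49e-05). The stress proteins Nupr1 and Ddit3 rose by 1.71 (SE 0.12, adjusted p = 1.40e-06) and 1.80 (SE 0.37, adjusted p = 0.0057), and the amino acid transporter subunit Slc3a2 by 1.21 (SE 0.24). Slc7a7, another such subunit, rose by 2.34 (SE 0.21) from a level near the background, and its limited rise of 0.50 did not pass (adjusted p = 0.0674). Of the ATF4 list 14 of 40 members rose and 0 fell (24 and 0 adjusted over the list alone). Their median was 0.85 (camera adjusted p = 1.45e-12, and adjusted p = 0.6297 with an estimated correlation). The 14 members became 7 without monuron 24 h replicate 1, 2 or 3 or DMSO 24 h replicate 1 or 2, 9 without DMSO 24 h replicate 3 or DMSO 6 h replicate 2, and 25 or 36 without DMSO 72 h replicate 1 or 3. The clock genes Per2, Per3 and Dbp rose by 2.12 (SE 0.35), 1.28 (SE 0.23) and 1.33 (SE 0.18). Of 15 circadian genes 7 rose and 0 fell (8 and 0 adjusted over the list alone). Their median was 0.62, or 0.37 limited (camera adjusted p = 7.74e-05, and adjusted p = 0.3714 with an estimated correlation). Of 7 targets of the aryl hydrocarbon receptor 3 rose and 1 fell (3 and 1 adjusted over the list alone), with Tiparp higher by 0.55 (SE 0.09) beside Cyp1a1 (median 0.27, camera adjusted p = 0.0206, and adjusted p = 0.3714 with an estimated correlation). The member that fell was Cyp1b1 (-0.65, SE 0.19, adjusted p = 0.0318), which was not called without monuron 24 h replicates 1, 2 or 3 (0.1267, 0.0646 and 0.0576) or DMSO 24 h replicates 1 or 2 (0.1369 and 0.1165).

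Part of the genes for DNA replication and of the heat shock genes were lower at 24 h. Ccne1, the cyclin that opens S phase, fell by 1.06 (SE 0.12, adjusted p = 1.02e-04), as did the flap endonuclease Fen1 (-0.81, SE 0.09) and the replication clamp Pcna (-0.36, SE 0.06). Of 41 replication genes 16 fell and 0 rose (18 and 0 adjusted over the list alone). Their median was -0.39 (camera adjusted p = 4.21e-09, and adjusted p = 0.5157 with an estimated correlation). Of 44 mitotic genes only Cks2, Ccnb1 and Cdc20 passed, all lower (3 and 0 adjusted over the list alone). Cdc20 was not called without any 1 of the 6 arrays of 24 h (adjusted p from 0.0651 to 0.1061), and Ccnb1 not without 5 of them, DMSO 24 h replicate 3 being the exception (0.0589 to 0.1108). The 3 mitotic genes became 6 or 19 without monuron 72 h replicate 1 or 3 and 6 without DMSO 72 h replicate 1 or 3. The median of the 44 genes was -0.31 (camera adjusted p = 6.43e-05, and adjusted p = 0.7129 with an estimated correlation). Heat shock genes fell in 5 of 15 cases and rose in 0 (6 and 0 adjusted over the list alone), such as the co-chaperone Dnajb1 with -0.53 (SE 0.11, adjusted p = 0.0062), with a list median of -0.25 (camera adjusted p = 0.0092, and adjusted p = 0.6083 with an estimated correlation). The 16 replication genes became 10 without DMSO 24 h replicate 2, and the 5 heat shock genes 3 without DMSO 24 h replicate 1. The transferrin receptor Tfrc fell by 1.51 (SE 0.33, adjusted p = 0.0086), as did the lactate dehydrogenase Ldha (-0.66, SE 0.08) and the collagen Col14a1 (-2.19, SE 0.30, adjusted p = 3.91e-04).

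At 24 h limma called 1227 of 9042 genes, 581 higher and 646 lower, and 144 changed at least 2-fold. The count was 589, 524 or 614 without monuron 24 h replicate 1, 2 or 3, 458 or 551 without DMSO 24 h replicate 1 or 2, and 2056 without DMSO 72 h replicate 3. In fits without any 72 h array, chosen after the data had been seen, 2048 genes were called at 6 h and 2993 at 24 h.

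**Figure D2:**
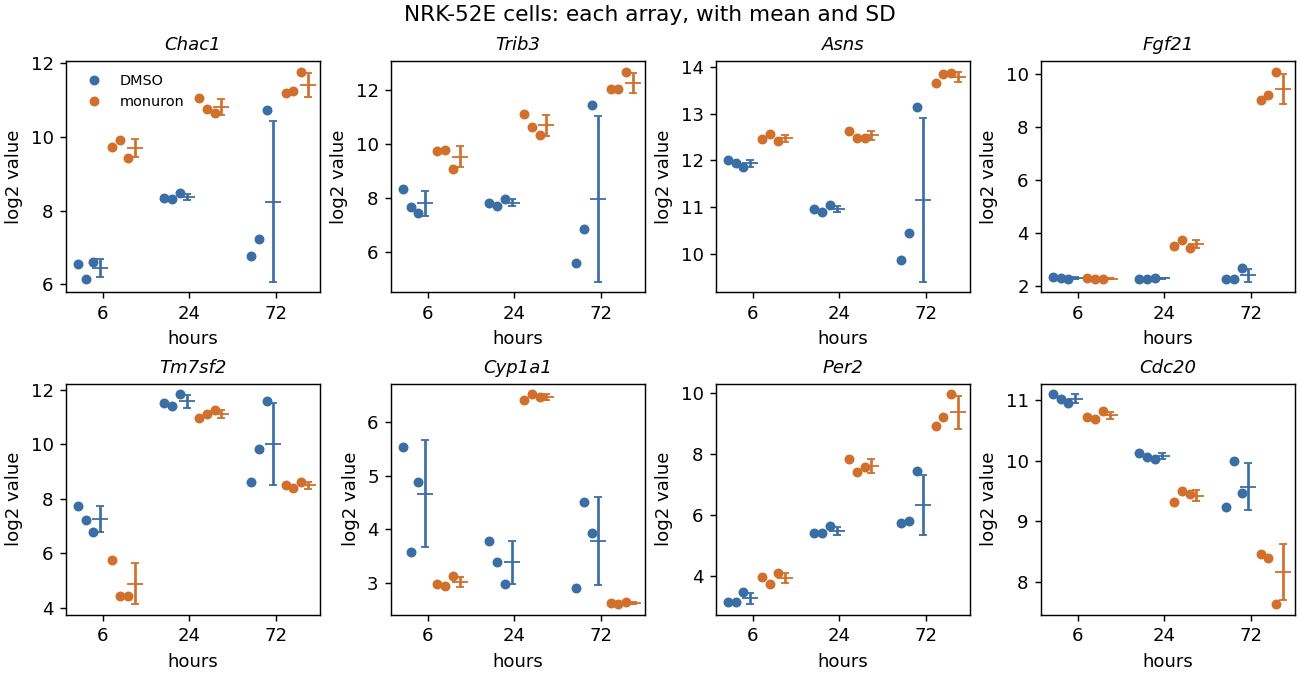
Log2 values of 8 genes in NRK-52E cells (vertical axes) at 6, 24 and 72 h (horizontal axes), each point 1 array, with the mean and SD of 3 arrays beside it, DMSO in blue and monuron in orange. Fgf21 with monuron reached a mean of 9.44 at 72 h against 2.40 with DMSO, and 1 DMSO array at 72 h, with Trib3 at 11.44, lies toward the monuron arrays.

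After 72 h most genes of the response to amino acid shortage were higher with monuron. Fgf21, a hormone that ATF4 induces, rose by 7.05 (SE 0.23, adjusted p = 6.70e-12; 9.44 ± 0.57 SD against 2.40 ± 0.24, n = 3 against 3; limited 5.31), the pseudokinase Trib3 by 4.28 (SE 0.91, adjusted p = 7.76e-04), and the asparagine synthetase Asns by 2.62 (SE 0.51, adjusted p = 3.29e-04). Of the ATF4 list 36 of 40 members rose and 1 fell, with the same counts adjusted over the list alone and a median of 1.73 (camera adjusted p = 1.33e-09, and adjusted p = 0.6297 with an estimated correlation). Chaperones of the endoplasmic reticulum rose in 22 of 24 cases and fell in 0 (22 and 1 adjusted over the list alone). Their median was 0.89 (camera adjusted p = 6.08e-07, and adjusted p = 0.6297 with an estimated correlation). Among them Sdf2l1 rose by 2.16 (SE 0.26), Dnajb9 by 2.01 (SE 0.23) and Dnajc3 by 1.67 (SE 0.19). DMSO 72 h replicate 3 stood apart in these genes: Trib3 was at 11.44 there against 5.60 and 6.86 in replicates 1 and 2 and 12.03 to 12.67 with monuron. On an axis of 1918 genes from the other DMSO arrays (0) to the monuron mean (1), that array lay at 0.454.

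Mitotic genes were lower at 72 h. Mki67, a marker of dividing cells, fell by 1.38 (SE 0.12, adjusted p = 4.03e-07), as did the survivin gene Birc5 (-1.54, SE 0.17) and Cdca3 (-2.21, SE 0.24). Of 44 mitotic genes 38 fell and 0 rose (40 and 1 adjusted over the list alone). Their median was -1.07 (camera adjusted p = 4.21e-09, and adjusted p = 0.6297 with an estimated correlation). Col14a1 fell by 6.04 (SE 0.30, adjusted p = 2.39e-09; limited -4.79), as did the matricellular gene Ccn5 (-3.99, SE 0.22; limited -2.37) and the stem cell factor gene Kitlg (-3.99, SE 0.39). The transferrin receptor Tfrc fell by 4.10 (SE 0.33, adjusted p = 1.61e-07). Clock genes moved in both directions, with Per2 and Cry1 higher by 3.04 (SE 0.35) and 2.51 (SE 0.26) and Tef lower (-2.92, SE 0.31, adjusted p = 1.63e-06). Of 15 circadian genes 10 rose and 1 fell, with the same counts adjusted over the list alone (median 1.05, camera adjusted p = 0.0183, 0.1515 without the filter on dim probe sets, and adjusted p = 0.5157 with an estimated correlation). The NRF2 targets Hmox1 and Srxn1 rose by 2.21 (SE 0.44) and 2.24 (SE 0.28). Of 22 NRF2 targets 13 rose and 5 fell, with the same counts adjusted over the list alone, but the list did not pass (median 0.65, camera adjusted p = 0.1193, and adjusted p = 0.6367 with an estimated correlation). Mdm2, a target of p53, rose by 1.59 (SE 0.15, adjusted p = 4.91e-07).

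At 72 h limma called 5572 of 9042 genes (61.6%), 2774 higher and 2798 lower, and 1495 changed at least 2-fold. Which direction held more genes depended on the processing: with arrays centred on their medians the split was 3111 higher and 2297 lower, and without the filter 3623 and 2743. The count was 5554 without both 72 h arrays of replicate 3, an alternative chosen after the data had been seen.

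The interaction tests asked whether the difference between monuron and DMSO itself changed with time. From 6 h to 24 h it changed for 110 genes, 58 upward and 52 downward, among them Cyp1a1 (4.74, SE 0.58, adjusted p = 0.0015, n = 3 per group). Cyp1a1 lay below the array medians with monuron at 6 h (3.01) and with DMSO at 24 h (3.39), and its limited change was 3.09 (adjusted p = 7.13e-04). Its monuron difference was -1.66 at 6 h (SE 0.41, adjusted p = 0.0266), where the limited difference of -0.75 did not pass (adjusted p = 0.0808). At 72 h the gene was near the background in both groups, so no difference is given. The 6 h call of Cyp1a1 was lost without monuron 6 h replicates 1, 2 or 3 (0.0639, 0.1061 and 0.0780) or DMSO 6 h replicates 1 or 3 (0.1492 and 0.0700). Tmem86a, which encodes a lysoplasmalogenase-like membrane protein (1.68, SE 0.19, adjusted p = 0.0012), also turned upward, and the actin crosslinker Flna turned downward (-0.72, SE 0.11, adjusted p = 0.0076). Slc7a7 changed by 2.34 (SE 0.29), but its limited change of 0.43 did not pass (adjusted p = 0.3599).

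From 24 h to 72 h the difference changed for 3423 genes, 1655 upward and 1768 downward, a balance that turned to 1875 and 1366 with arrays centred on their medians. Fgf21 changed by 5.76 (SE 0.32; limited 5.31), Reep6, a shaping protein of the endoplasmic reticulum, by 3.95 (SE 0.31; limited 1.82), Sar1a, which builds the vesicles that leave it, by 1.68 (SE 0.12). Gla, a lysosomal galactosidase, changed by -2.02 (SE 0.17) and Ccn5 by -3.54 (SE 0.31; limited -1.93). The adjusted p of these 5 genes was at most 7.47e-06. Fgf21 was dim in DMSO cells (2.27 at 24 h), and its change was not called with a filter at the 75th percentile (adjusted p = 0.0785). Chaperones of the endoplasmic reticulum changed upward in 16 of 24 cases and downward in 0 (17 and 0 adjusted over the list alone). Their median was 0.83 (camera adjusted p = 1.57e-05, and adjusted p = 0.6932 with an estimated correlation). Mitotic genes changed downward in 25 of 44 cases and upward in 0 (28 and 0 adjusted over the list alone). Their median was -0.78 (camera adjusted p = 6.04e-06, and adjusted p = 0.7534 with an estimated correlation). Without DMSO 72 h replicate 2 the 25 became 16. From 6 h to 72 h it changed for 4267 genes, 2102 upward and 2165 downward, with Col14a1 at -5.52 (SE 0.42; limited -4.26) and the methyl-CpG binding gene Mbd5 at -3.87 (SE 0.27). Centring arrays on their medians moved the median of all genes in that last contrast from 0.01 to 0.17 and the split to 2700 and 1535.

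The count for 24 h minus 6 h depended on single arrays. Its count of 110 was 429 with the replicate block and 1642 without the 72 h arrays. It was 63, 17 or 22 without monuron 6 h replicate 1, 2 or 3, 29 or 23 without DMSO 6 h replicate 1 or 2, 21, 16 or 25 without monuron 24 h replicate 1, 2 or 3, and 15, 22 or 54 without DMSO 24 h replicate 1, 2 or 3. It was 226 without monuron 72 h replicate 3 and 426 or 589 without DMSO 72 h replicate 1 or 3.

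DMSO cells also changed with time in culture. Between 6 h and 24 h, 37 of 41 replication genes fell and 1 rose (39 and 1 adjusted over the list alone). Their median was -1.17 (camera adjusted p = 1.83e-13, and adjusted p = 0.3678 with an estimated correlation). The 1 that rose became 0 without DMSO 6 h replicate 1 or 2 or DMSO 24 h replicate 1 or 2. Of 44 mitotic genes 39 fell and 0 rose (41 and 0 adjusted over the list alone). Their median was -1.07 (camera adjusted p = 7.09e-11, and adjusted p = 0.6932 with an estimated correlation). The RNA helicase Ddx39a fell by 1.85 (SE 0.10), and Trip13, which acts in the mitotic checkpoint, fell by 1.58 (SE 0.09). The lysosomal genes Lamp2 and Ctsd rose by 0.88 (SE 0.04) and 1.18 (SE 0.06). The adjusted p of these 4 genes was at most 5.02e-09. Between 24 h and 72 h genes of cholesterol synthesis and uptake fell in 14 of 23 cases and rose in 1 (15 and 1 adjusted over the list alone). Their median was -1.03 (camera adjusted p = 5.26e-04, and adjusted p = 0.7253 with an estimated correlation). The 14 became 5, 4 or 6 without DMSO 24 h replicate 1, 2 or 3 and 8 or 9 without DMSO 72 h replicate 1 or 2. The 1 that rose became 0 without DMSO 24 h replicate 1 or 3 or DMSO 72 h replicate 1. Over this span Nupr1 rose by 2.00 (SE 0.12), the complement regulator Cd55 by 2.82 (SE 0.21), and Sfn, the epithelial 14-3-3 protein, fell by 3.41 (SE 0.29). In all 4800 genes changed from 6 h to 24 h (2239 higher, 2561 lower), 2526 from 24 h to 72 h (1046 and 1480) and 5595 from 6 h to 72 h (2430 and 3165). Centring arrays on their medians moved the median of all genes from -0.03 to -0.15 in the first contrast and from -0.08 to -0.21 in the last, and the split to 1666 higher and 3242 lower in the first and to 1901 and 3744 in the last.

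**Figure D3:**
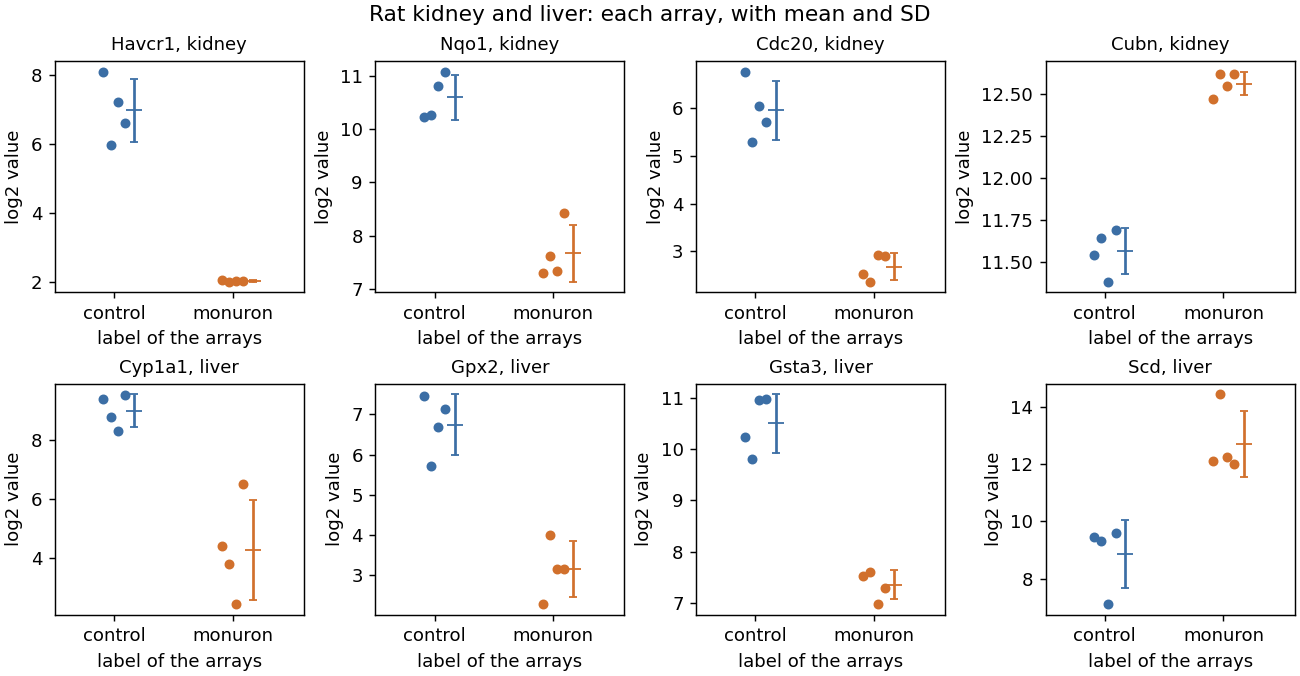
Log2 values of 4 kidney genes and 4 liver genes (vertical axes) in the arrays labelled control (blue) and monuron (orange), each point 1 rat, with the mean and SD of 4 rats beside it. Havcr1 in kidney lies at 2.03 in the monuron group and at 6.99 in the control group, and Scd in liver has 1 array apart from the others in each group.

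In kidney, Havcr1, part of the targets of NRF2 and most genes of cell division were lower in the arrays labelled monuron than in those labelled control. Havcr1, the kidney injury molecule that damaged proximal tubules express, fell by 4.96 (SE 0.38, adjusted p = 2.64e-04; 2.03 ± 0.02 SD against 6.99 ± 0.91, n = 4 against 4). The monuron value lay below the 25th percentile of those arrays (2.387 to 2.447), at the background, so that the size is uncertain. The limited difference was -3.07 (adjusted p = 0.0022). Of 27 kidney injury markers 5 fell and 2 rose, with the same counts adjusted over the list alone, and the list did not pass (median -0.29, camera adjusted p = 0.1094, and adjusted p = 0.6297 with an estimated correlation). The stress hormone Gdf15 fell by 3.28 (SE 0.43, adjusted p = 0.0031; limited -2.90). Of 36 mitotic genes 33 fell and 0 rose (34 and 1 adjusted over the list alone). Their median was -2.45, or -2.16 limited (camera adjusted p = 7.29e-22, and adjusted p = 0.5157 with an estimated correlation). Examples are Cdc20 with -3.28 (SE 0.30; limited -2.04), Kif22 with -3.30 (SE 0.26) and Mki67 with -2.07 (SE 0.37, adjusted p = 0.0111). Of 28 replication genes 10 fell and 1 rose (19 and 1 adjusted over the list alone). Their median was -0.56 (camera adjusted p = 6.43e-05, and adjusted p = 0.6297 with an estimated correlation). Nqo1, a quinone reductase under the transcription factor NRF2, fell by 2.93 (SE 0.27, adjusted p = 9.22e-04), as did the sulfiredoxin gene Srxn1 (-3.49, SE 0.46) and Gpx2, a glutathione peroxidase (-1.97, SE 0.23). Of 25 NRF2 targets 11 fell and 0 rose (14 and 2 adjusted over the list alone). Their median was -0.45 (camera adjusted p = 0.0019, and adjusted p = 0.6367 with an estimated correlation). Of 19 glutathione and glucuronosyl transferases 7 fell and 0 rose (12 and 0 adjusted over the list alone). Their median was -0.34 (camera adjusted p = 0.0045, and adjusted p = 0.6297 with an estimated correlation). Ugt2b7 among them was at -3.98 (SE 0.43). Immediate early genes fell in 8 of 26 cases and rose in 0 (14 and 0 adjusted over the list alone). Their median was -0.45 (camera adjusted p = 2.72e-05, and adjusted p = 0.6083 with an estimated correlation). Examples are Myc with -2.27 (SE 0.30) and Egr1 with -2.03 (SE 0.35). Of these counts, the 10 replication genes became 6, 6 or 5 without kidney monuron replicate 1, 2 or 3 and 4 without kidney control replicate 3, where the 1 that rose became 0. The 7 transferases became 3, 3 or 2 without kidney monuron replicate 1, 2 or 3 and 3, 3, 2 or 2 without kidney control replicate 1, 2, 3 or 4. The 8 immediate early genes became 5 without kidney monuron replicate 3 or kidney control replicate 3 or 4. The 5 injury markers became 3 without kidney monuron or control replicate 3, and the 2 that rose became 1 without kidney monuron replicate 1 or 3 or kidney control replicate 1, 3 or 4.

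Part of the genes for transporters and enzymes of the proximal tubule were higher in the kidneys labelled monuron. The endocytic receptor Cubn rose by 1.01 (SE 0.08, adjusted p = 2.52e-04; 12.57 ± 0.07 SD against 11.56 ± 0.14, n = 4 against 4), the aminopeptidase Anpep by 0.83 (SE 0.12, adjusted p = 0.0041) and the organic anion transporter Slco1a1 by 2.32 (SE 0.28, adjusted p = 0.0022). Of 48 proximal tubule genes 10 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.16 against -0.08 for the other genes (camera adjusted p = 4.21e-09, and adjusted p = 0.3714 with an estimated correlation). Large rises were also seen in Dpyd, which degrades pyrimidines (2.83, SE 0.13, adjusted p = 1.93e-05), and Acadsb, an acyl-CoA dehydrogenase (2.41, SE 0.39, adjusted p = 0.0072). Cytosolic ribosomal protein genes fell in 11 of 36 cases and rose in 0 (27 and 0 adjusted over the list alone). Their median was -0.18 (camera adjusted p = 3.55e-07, and adjusted p = 0.5157 with an estimated correlation). The 11 became 5 or 2 without kidney monuron replicate 1 or 3 and 3 or 6 without kidney control replicate 3 or 4. The 10 proximal tubule genes became 6 without kidney monuron replicate 3 and 5 or 6 without kidney control replicate 3 or 4, and the 1 that fell became 3 without kidney monuron replicate 4. Cyp1a1 differed by -0.16 (SE 0.77, adjusted p = 0.9167).

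In kidney limma called 974 of 9542 genes, 369 higher and 605 lower, with 159 changed at least 2-fold. The count was 596 or 396 without monuron kidney replicate 1 or 3 and 370 without control kidney replicate 3.

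In liver part of the genes of detoxification were lower in the arrays labelled monuron. Cell type markers moved in the same arrays: the medians were 0.04 for 29 hepatocyte markers, 0.29 for leukocyte, 0.21 for fibroblast, stellate and smooth muscle and 0.10 for endothelial markers, against -0.07 for the other genes. Camera called these 4 lists higher (adjusted p = 0.0491, 1.72e-08, 0.0183 and 0.0118), but not with an estimated correlation (0.5312, 0.5157, 0.6297 and 0.5157). Gsta3, a glutathione transferase, fell by 3.14 (SE 0.27, adjusted p = 0.0016; 7.35 ± 0.28 SD against 10.49 ± 0.57, n = 4 against 4), and the aldehyde reductase Akr7a3 fell by 2.15 (SE 0.18, adjusted p = 0.0016). The retinal dehydrogenase Aldh1a1 fell by 2.02 (SE 0.11, adjusted p = 1.20e-04) and the epoxide hydrolase Ephx1 fell by 0.78 (SE 0.06). Of 25 NRF2 targets 12 fell and 0 rose, with the same counts adjusted over the list alone (median -0.54, camera adjusted p = 4.21e-09, and adjusted p = 0.3605 with an estimated correlation). Of 24 glutathione and glucuronosyl transferases 9 fell and 0 rose (13 and 2 adjusted over the list alone). Their median was -0.41 (camera adjusted p = 5.48e-06, and adjusted p = 0.5157 with an estimated correlation). Targets of PPARalpha fell in 8 of 31 cases and rose in 0 (15 and 0 adjusted over the list alone), among them Creg1 (-0.64, SE 0.06, adjusted p = 0.0016), and the list median was -0.29 (camera adjusted p = 1.30e-05, and adjusted p = 0.3714 with an estimated correlation). The 8 became 1, 5 or 3 without liver monuron replicate 1, 2 or 3 and 1, 1 or 4 without liver control replicate 1, 2 or 4. The 12 NRF2 targets became 6 or 7 without liver monuron replicate 1 or 3 and 6 without liver control replicate 1. Cyp1a1 fell by 4.71 (SE 0.73, adjusted p = 0.0196), a call that ended without monuron liver replicate 1 (0.0628) or control liver replicate 1, 2 or 4 (0.0716, 0.0580 and 0.0604). Cyp1a2, the related hepatic enzyme, differed by -0.25 (SE 0.15, adjusted p = 0.3220).

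A few lipid synthesis genes were higher in liver. Scd, the stearoyl-CoA desaturase, rose by 3.83 (SE 0.67, adjusted p = 0.0264), a call that ended without monuron liver replicate 1 or 3 (0.0709 and 0.0670) or control liver replicate 1, 2 or 4 (0.0763, 0.0682 and 0.0604). Of 24 genes of fatty acid synthesis only Scd, Acly and Thrsp passed, all higher (7 and 1 adjusted over the list alone). Acly was not called without liver monuron replicate 1, 2 or 3 or liver control replicate 1 or 4 (adjusted p from 0.0743 to 0.1169), and Thrsp not without any 1 of the 8 arrays (0.0552 to 0.1335). The list median was 0.29 (camera adjusted p = 3.86e-04, and adjusted p = 0.5157 with an estimated correlation). Of 23 genes of cholesterol synthesis and uptake only Insig1 passed, higher (6 and 0 adjusted over the list alone). It was not called without any 1 of the monuron arrays or without liver control replicate 1 or 4 (0.0533 to 0.1169). Without liver monuron replicate 2 there were 2 other calls in the list. The median of the list was 0.28 (camera adjusted p = 5.55e-05, and adjusted p = 0.6083 with an estimated correlation). The fatty acid binding gene Fabp5 rose by 1.59 (SE 0.19, adjusted p = 0.0087) and the complement gene C6 by 1.70 (SE 0.20, adjusted p = 0.0087). In liver limma called 292 of 9361 genes, 103 higher and 189 lower, with 48 changed at least 2-fold. The count was 34, 145 or 63 without monuron liver replicate 1, 2 or 3, and 40, 54, 504 or 52 without control liver replicate 1, 2, 3 or 4.

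The treatment difference itself differed between the organs for 271 of 10116 genes, 110 higher and 161 lower in liver minus kidney. Havcr1 (4.97, SE 0.42, adjusted p = 1.21e-05, n = 4 per group; limited 3.10), the mitotic motor Kif22 (3.12, SE 0.31) and Abcc2, a pump for conjugates (3.32, SE 0.38), differed upward, with changes of -4.96, -3.30 and -2.63 in kidney. Aldh1a1 differed by -1.87 (SE 0.12, adjusted p = 4.52e-07), with a change of -2.02 in liver. Of 36 mitotic genes 19 differed upward and 0 downward (32 and 1 adjusted over the list alone). Their median was 2.07, or 1.78 limited (camera adjusted p = 1.02e-30, and adjusted p = 0.3678 with an estimated correlation). The mitotic genes of the fixed panel were dim in liver. Ccnb1 was at 3.93 with monuron and 4.44 with control, Top2a at 3.76 and 4.30, and Mki67 at 4.90 and 5.26. The medians of the liver arrays were 3.670 to 3.783, and Havcr1 lay below them in both groups. For such genes a smaller response in liver cannot be told apart from a level too low to fall. Of 29 kidney injury markers 3 differed upward and 0 downward (9 and 1 adjusted over the list alone). Their median was 0.45 (camera adjusted p = 5.34e-06, and adjusted p = 0.3013 with an estimated correlation). The count was 154 without kidney monuron replicate 3, 159 without kidney control replicate 3, and 175 or 500 without liver control replicate 1 or 3.

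Genes called in both organs mostly moved the same way. Of 8804 genes tested in both, 36 fell in both against 11.2 expected by chance (one-sided Fisher's exact p = 2.89e-10, adjusted p = 2.31e-09), among them Gsta3, Gpx2, Ephx1 and Creg1. Higher in both were 22 against 3.3 expected (Fisher's exact p = 9.17e-13, adjusted p = 1.47e-11), such as the growth hormone receptor Ghr (0.66 in kidney, SE 0.08, and 0.48 in liver, SE 0.07), Fhit, a dinucleotide hydrolase (2.29 and 1.11), and Mmut, the methylmalonyl-CoA mutase (0.91 and 0.49). Only 4 genes were called in opposite directions, the carnitine transporter Slc22a5, Decr2 and Abhd14a higher in kidney and lower in liver, and Anxa1 the reverse. The 58 genes that shared a direction were 93.5% of the 62 called in both. The numbers hint that both organs came from the same rats, which would make agreement more common than the expected counts assume. In other splits of the rats, the first 974 kidney and 292 liver genes shared a direction for a median of 28 and at most 51 genes, a test chosen after the result had been seen. Their like-signed share had a median of 79.0% and reached 97.8%, so the Fisher's exact p-values overstate the evidence. The 58 became 33 or 30 without kidney monuron or control replicate 3, 11, 29 or 19 without liver monuron replicate 1, 2 or 3, and 12, 15 or 16 without liver control replicate 1, 2 or 4.

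Genes called in the cell line were also compared with those called in kidney, over 8083 genes tested in both. With the 24 h cells, 74 genes were lower in both against 41.3 expected (one-sided Fisher's exact p = 3.57e-07, adjusted p = 1.90e-06), among them the replication and chromatin genes Mcm7, Nasp and H2ax, and 22 were higher in both against 15.2 (p = 0.0514, adjusted p = 0.1372). At an adjusted p threshold of 0.01 lower in both were 7 against 2.7 (Fisher's exact p = 0.0173). Without the filter they were 44 against 15.1 (Fisher's exact p = 1.88e-10), but 23 genes were then also higher in cells and lower in kidney against 13.4 (p = 0.0085). With the 6 h cells 20 genes were lower in both against 17.5 (Fisher's exact p = 0.2990) and 8 higher in both against 8.0 (p = 0.5576).

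With the 72 h cells the direction of the sharing depended on the setting. At the threshold used here 221 genes were higher in cells and lower in kidney against 178.1 expected (Fisher's exact p = 4.44e-05, adjusted p = 1.78e-04), among them Srxn1 and the matricellular gene Ccn1. Conversely, 96 were lower in cells and higher in kidney against 74.2 (Fisher's exact p = 0.0015, adjusted p = 0.0049), among them the aldehyde dehydrogenase Aldh2 and Hsd17b4, an enzyme of peroxisomal beta-oxidation. Lower in both at 72 h were 155 genes against 175.8 (Fisher's exact p = 0.9783), among them the mitotic genes Cdc20, Knstrn and Ccnb2. At an adjusted p threshold of 0.01 this turned: lower in both were 43 against 26.9 (Fisher's exact p = 4.49e-04), and higher in cells and lower in kidney were 25 against 27.6 (p = 0.7506). Without the filter all these directions were above expectation, with 126 lower in both against 84.9 (Fisher's exact p = 9.94e-07), 146 higher in cells and lower in kidney against 112.1 (p = 1.50e-04) and 62 the reverse against 46.9 (p = 0.0099). With the 6 h cells 28 genes shared a direction and 17 did not (two-sided Fisher's exact p = 0.1915), with the 24 h cells 96 and 48 (p = 5.44e-04), and with the 72 h cells 213 and 317 (p = 1.03e-05).

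These overlaps depended on single arrays. The 28 genes at 6 h became 18, 6 or 8 without monuron 6 h replicate 1, 2 or 3, 6 or 18 without DMSO 6 h replicate 1 or 3, 44 or 52 without DMSO 72 h replicate 1 or 3, 15 or 5 without kidney monuron replicate 1 or 3, and 5 or 16 without kidney control replicate 3 or 4. The 96 genes at 24 h became 61, 47 or 58 without monuron 24 h replicate 1, 2 or 3, 41 or 49 without DMSO 24 h replicate 1 or 2, 50 or 29 without kidney monuron replicate 1 or 3, and 28 without kidney control replicate 3. Among the 24 h genes the 74 lower in both became 22 or 19 without kidney monuron or control replicate 3, where the sharing missed the threshold (Fisher's exact p = 0.0638 and 0.1328). The 221 genes higher in the 72 h cells and lower in kidney became 138 or 75 without kidney monuron replicate 2 or 3 (Fisher's exact p = 0.0539 and 0.1425). They became 145, 140 or 72 without kidney control replicate 1, 2 or 3 (Fisher's exact p = 0.0808, 0.1054 and 0.0781). The 213 genes at 72 h became 107 or 102 without kidney monuron or control replicate 3.

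**Figure D4:**
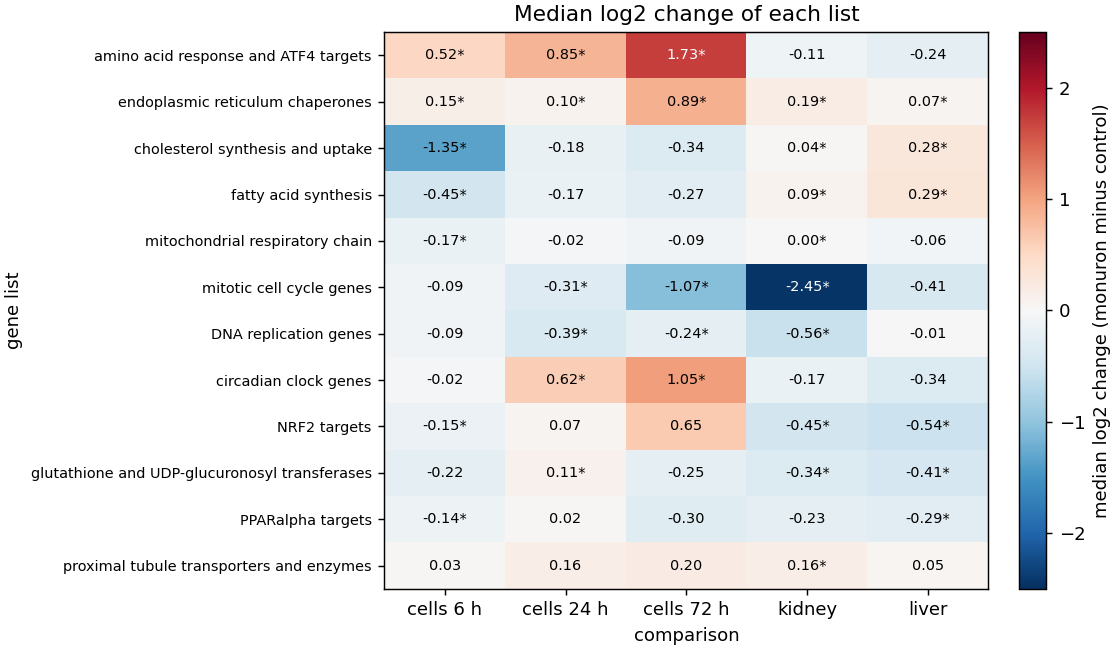
Median log2 change of 12 of the gene lists (vertical axis) in the 5 main comparisons (horizontal axis), with colour and number giving the median and an asterisk for a camera call at the preset correlation. ATF4 targets rise from 0.52 to 1.73 over time in the cells, and mitotic genes are lowest in kidney with -2.45; 0 of the calls hold with an estimated correlation.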

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

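The tests of leukocyte markers in kidney, of the 72 h DMSO array, of the 72 h arrays in the earlier fits, of exchanged times, of the animal block and of the first genes and the share of like signs in other splits of the rats were chosen only after the results had been seen, and the tests of label exchange in the rats and of the other regrouped arrays were written before.

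In the rats part of the NRF2 targets were higher in the arrays labelled control, 11 of 25 in kidney and 12 of 25 in liver, although the list did not pass with an estimated correlation (adjusted p = 0.6367 and 0.3605). The 12 became 6 or 7 without liver monuron replicate 1 or 3 and 6 without liver control replicate 1. In kidney so were most mitotic genes, 33 of 36, and Havcr1, at 6.99 against 2.03 in those labelled monuron. A candidate explanation is an exchange of the treatment labels between the sets of rats, which predicts that genes called in the 24 h cells are shared with kidney in opposite directions. The prediction needs cells and kidney to respond alike to the same compound. The compound on the cells is in doubt, and with another neither outcome would bear on the rat labels. At 24 h 96 genes were shared in the same direction and 48 in opposite directions, which met the bound set against the exchange at adjusted p thresholds of 0.05 and 0.01. That bound was too weak for 3 reasons. Without the filter it was not met, as 23 genes were higher in cells and lower in kidney against 13.4 expected. Of 1105 genes called in the 24 h cells 57.0% had the same sign in kidney, and 9 of 35 splits of the kidneys, the real one included, gave a share as far from 50%, up to 58.1%. At 72 h the sharing was opposite with 221 genes against 178.1 expected, but in the same direction at a threshold of 0.01 (43 lower in both against 26.9). Exchanged and correct labels therefore cannot be told apart, nor more leukocytes in the kidneys labelled control from an equal share. The median of the leukocyte list was 0.107, but 16 of 27 members were higher and 11 lower in the kidneys labelled monuron, with quartiles of -0.07 and 0.19. Its 3 calls were all higher (Coro1a, Ptprc and Lcp1), and with 1 array left out 0 to 2 members were called higher and up to 1 lower. Ptprc was not called without 7 of the 8 arrays (adjusted p from 0.0572 to 0.1143), all but monuron replicate 4. Coro1a was not called without monuron replicates 1, 2 or 3 or control replicates 2, 3 or 4 (0.0591 to 0.1038). The treatment as labelled remains open and was not tested apart from the labels.

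DMSO 72 h replicate 3 lay at 0.454 on the axis from the other DMSO arrays at 72 h (0) to the monuron mean (1), with the other DMSO arrays at -0.060 and 0.060. RNA of monuron cells mixed into it is argued against by the 199 genes at least 4-fold higher with monuron: at the median share of 0.343 that they imply, 34 lay under 50% of the level needed, against 2, 0 and 2 genes in the monuron arrays (Fgf21 was at 2.67 there and at 9.44 on average with monuron). An exchange with a monuron array is argued against because the lowest monuron array lay at 0.892 and so none was out of place. A culture run shared by the arrays of 1 number may account for it: the deviations of the arrays of replicate 3 correlated at 0.317, above the highest value of 0.275 between unlike numbers, and the other same-numbered pairs at 0.205 and 0.167. No biological explanation was tested for this array.

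Fewer genes were called at 6 h (571) and 24 h (1227) than at 72 h (5572). The spread of the 72 h arrays, pooled into the earlier comparisons, may be part of this. Fits of the arrays of 1 time alone, which have the same form at each time, gave 1355 genes at 6 h, 3240 at 24 h and 3719 at 72 h. With 1 array left out they gave 240 to 1224, 2023 to 3415 and 1680 to 4672. At 24 h these ranges overlap those of 72 h, but the 72 h minus 24 h interaction held 3423 genes. At 6 h each count stayed below each of 72 h. Both argue against the spread as the whole cause. The longer exposure is the biological explanation in the design and stays open.

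These differences between times or organs passed an interaction test. The effect of monuron changed from 6 h to 24 h for 110 of 9042 genes, with Cyp1a1 at 4.74, Tmem86a at 1.68, Slc7a7 at 2.34 (not past the threshold with values limited at the array median), Ninl at -0.87 and Flna at -0.72. It changed from 24 h to 72 h for 3423 genes, with Fgf21 at 5.76, Sar1a at 1.68, Reep6 at 3.95, Gla at -2.02 and Ccn5 at -3.54. It changed from 6 h to 72 h for 4267 genes, with Fgf21 at 7.08, Sar1a at 1.74, Mbd5 at -3.87 and Col14a1 at -5.52. It differed between liver and kidney for 271 genes, with Havcr1 at 4.97, Kif22 at 3.12, Abcc2 at 3.32, Aldh1a1 at -1.87, Dpyd at -1.96, Fgf13 at -2.30 and Cyp1a1 at -4.55 (adjusted p = 0.0453). Havcr1 and Fgf13 lay below the array medians in both liver groups.

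Single arrays stood apart in 9 of 132 groups of 4 values by Dixon's ratio of gap to range, above its 95% critical value, and chance gives about 1 in 20 groups. In the monuron kidneys Dpyd was low in replicate 2 (7.86 against 8.28 to 8.34, ratio 0.886), Eml6 was high in replicate 1 (6.57 against 5.25 to 5.39, ratio 0.891) and Srxn1 was high in replicate 4 (7.81 against 5.40 to 5.79, ratio 0.836). In the control kidneys Gpx2 was high in replicate 3 (11.80 against 11.32 to 11.39, ratio 0.846). In the monuron livers Scd was high in replicate 2 (14.43 against 12.01 to 12.24, ratio 0.902), Aldh1a1 was low in replicate 4 (10.79 against 11.13 to 11.19, ratio 0.855) and Cyp1a2 was low in replicate 3 (13.93 against 14.51 to 14.61, ratio 0.852). In the control livers replicate 3 was low for Scd (7.11 against 9.30 to 9.59, ratio 0.885) and high for Slc25a20 (11.24 against 11.05 to 11.07, ratio 0.896).

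Probe sets with no gene symbol or with several, which the comparisons of genes do not use, also passed the threshold in a fit of all probe sets. They numbered 202 at 6 h (161 higher), 380 at 24 h (171 higher) and 1896 at 72 h (742 higher) of 3691 tested, 178 in kidney (93 higher) of 3215 and 57 in liver (28 higher) of 3338.

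Other splits of the same arrays were counted for each result, the real split included. With 3 arrays against 3 there are only 10 splits, too few for a share under 0.05: 1 of 10 gave a count as large in each case, with 571, 1227 and 5572 genes for 6, 24 and 72 h against at most 0, 0 and 64 in the other splits, and 4800, 2526 and 5595 for DMSO over time (24 h against 6 h, 72 h against 24 h, 72 h against 6 h) against at most 0, 1 and 0. Among the splits at 72 h that part every pair of numbers the highest other count was 0. For the interactions of 110, 3423 and 4267 genes (24 h minus 6 h, 72 h minus 24 h, 72 h minus 6 h) the draws of treatment labels planned before decide nothing. They remove the treatment effect itself and so do not test whether it was equal at both times. As large a count came in 2, 4 and 1 of 100 draws, and the highest others (544, 4050 and 4090) had kept the true grouping at 6 h and at 1 later time. Exchanging the times of numbered pairs, with each time centred, keeps an equal effect and the pairs. There are only 10 such exchanges, too few for a share under 0.05: 1 of 10 gave as many in each case, and the highest others gave 0, 1 and 0.

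In kidney 1 of 35 splits gave 974 genes (highest other 1), and in liver 1 of 35 gave 292 (highest other 2), so chance can be excluded at 0.05. For the organ difference 1 of 35 gave 271 (highest other 4), which decides nothing, as the other splits leave a treatment effect shared by the organs in the spread. With animal number as a block such an effect cancels within each rat: taking it out of the values changed the count in 0 of 35 splits. There 1 of 35 gave 193 (highest other 6), so chance can be excluded at 0.05 for that fit. For the overlaps of 58 genes between kidney and liver and of 28, 96 and 213 genes between cells and kidney the splits decide nothing: 1 of 35 gave as many, but the other splits call at most 1 kidney gene, which fixes their overlap at 0. Comparing the first 974 kidney and 292 liver genes needs no calls in the other splits. In 1 of 35 splits as many as 58 genes shared a direction, and the highest other gave 51 and the median 28. The other splits take the treatment effect out of both organs. They therefore exclude at 0.05 only that the labels have no bearing, and cannot decide on sharing apart from an effect within each organ. The share of like signs needs no calls either. Between genes called in the cells and kidney it was 51.5%, 57.0% and 47.1% at 6, 24 and 72 h, and 30, 9 and 17 of 35 splits of the kidneys gave a share as far from 50% (highest others 64.9%, 58.1% and 58.0%), so chance cannot be excluded. For the gene lists 1 of 100 draws gave the 58 calls, but the highest other draw gave 55 and the median draw 31, so a large number of camera calls at the preset correlation arises without the true grouping.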

How the results depend on the processing

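The fits without the 72 h arrays, the fits without both 72 h arrays of replicate 3, the list tests with a replicate block and the values limited at the array median were chosen after the data had been seen, and the other alternatives before. Of the named genes and the called lists 0 reversed. The overlap of the 72 h cells and kidney did change its balance: 213 genes shared a direction and 317 did not, while at an adjusted p threshold of 0.01 54 did and 40 did not. The larger of the counts higher and lower also changed sides, in 11 of 34 alternatives at 6 h, 4 of 34 at 24 h, 9 of 33 at 72 h, 7 of 32, 7 of 31 and 11 of 31 for the interactions, 3 of 30 for the organ difference, 2 of 32, 0 of 31 and 1 of 31 for DMSO, and 0 of 22 in kidney and in liver. Of 202 results for named genes, 5268 of the 5675 values under alternatives kept their direction and side of the threshold, 397 were no longer past it and 10 newly passed it (Trib3 and Asns at 6 h). The 58 list calls kept theirs in 2089 of 2204 values, apart from the estimated correlation and fry. Unless a count or its construction shows it (a stricter threshold, fewer or more probe sets tested), the cause was not tested. The alternative for values on a linear scale was not run because the values are log2. Signal near the background limits dim genes: with values limited at the array median the calls of Otub2, Cyp1a1 and Mgst1 at 6 h, Fgf21 and Slc7a7 at 24 h, Cyp1a1 at 72 h and Slc7a7 in the 24 h minus 6 h interaction ended (adjusted p from 0.0674 to 0.9967), because 1 or more of their groups lay below that median.

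Counts that moved by more than 1.5 times were as follows. With arrays centred on their medians, the 24 h minus 6 h interaction had 59 genes and liver 191. Without the filter liver had 95, the overlap of kidney and liver 19, and those of cells and kidney 16 at 6 h and 54 at 24 h. With every probe set on its own, counts of probe sets were 9043 at 72 h, 179 and 6758 for the interactions 24 h minus 6 h and 72 h minus 6 h, and 7538, 4290 and 9260 for DMSO (24 h against 6 h, 72 h against 24 h, 72 h against 6 h). Without the trend liver had 117. With array weights 6 h had 3873, 24 h 5240, the 24 h minus 6 h interaction 4159, DMSO 72 h against 24 h 1373, liver 761 and the organ difference 443.

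With a minimum of 2-fold the counts were 67, 144 and 1495 at 6, 24 and 72 h, 39, 1109 and 1491 for the interactions, 1029, 387 and 1665 for DMSO, 159 in kidney, 48 in liver and 130 for the organ difference. At an adjusted p threshold of 0.01 they were 110 at 6 h, 383 at 24 h, 13, 2037 and 2755 for the interactions, 1393 for DMSO 72 h against 24 h, 223 in kidney, 25 in liver and 78 for the organ difference, and the overlaps were 4 for kidney and liver and 0, 7 and 54 for cells and kidney at 6, 24 and 72 h.

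With the arrays of 1 time alone 6 h had 1355 and 24 h 3240. Without the 72 h arrays 6 h had 2048, 24 h 2993 and the 24 h minus 6 h interaction 1642. Without both 72 h arrays of replicate 3, 6 h had 1609 and 24 h 2494. With all 16 tissue arrays in the fit liver had 1178.

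With the replicate number within each time as a block, 6 h had 1030 genes and the 24 h minus 6 h interaction 429, and 24 h, 72 h, the other interactions and DMSO over time stayed within 1.5 times. At 6 h and 72 h this block changed no other call of a named gene, and of the lists it added that of transferases at 6 h. At 24 h, where the numbers did not pair, the list of glycolysis and hypoxia genes was lost (adjusted p = 0.1213). In kidney and liver treated and control rats share only a number: the block by number gave 350 and 40 genes, correlations of deviations were between -0.216 and 0.045, and 0 of 8 arrays in each organ correlated best with their own number. Between kidney and liver, 8 of 8 monuron arrays and 7 of 8 control arrays correlated best with their own number, with correlations from 0.021 to 0.158, a hint from the data that numbers mark animals. A block of animal number gave 193 genes (fixed) and 384 (random, correlation 0.096) for the organ difference.

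Leaving out 1 array at a time gave 103 to 1197 genes at 6 h, 458 to 2056 at 24 h, 4829 to 5970 at 72 h, 15 to 589, 2777 to 4411 and 3585 to 5080 for the interactions, 4197 to 5327, 1735 to 3403 and 5071 to 5843 for DMSO, 370 to 928 in kidney, 34 to 504 in liver and 154 to 500 for the organ difference. The overlaps ranged from 11 to 77 for kidney and liver, and from 5 to 52, 28 to 136 and 102 to 221 for cells and kidney at 6, 24 and 72 h. Of the lists 52 to 60 were called, a narrow range because a left-out array changed only the list tests of its own sample type. With an estimated correlation 0 lists were called and with fry 41, of which 27 were also called by camera.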

Other observations

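For further gene groups the values follow the named gene rule and the lists written before the data were examined. The splits of the share of like signs were chosen only after the result had been seen. In kidney, transcripts that are typical of hepatocytes moved in both directions. The plasma glycoprotein Apoh was higher in the arrays labelled monuron by 2.21 (SE 0.34, adjusted p = 0.0059, n = 4 against 4) and the vitamin D carrier Gc by 1.80 (SE 0.24, adjusted p = 0.0035; 12.52 ± 0.41 SD against 10.71 ± 0.43), while the cytochrome P450 gene Cyp2e1 fell by 0.88 (SE 0.14, adjusted p = 0.0061). Of 15 measured hepatocyte markers 3 rose and 1 fell (5 and 2 adjusted over the list alone), and the list did not pass (median 0.10, camera adjusted p = 0.0643, and adjusted p = 0.6297 with an estimated correlation). Of 9 genes that differ between male and female liver, 3 rose in kidney and 0 fell (4 and 1 adjusted over the list alone; median 0.34, camera adjusted p = 0.0214, and adjusted p = 0.5157 with an estimated correlation), among them the transporter Slco1a1 (2.32, SE 0.28). The 3 became 1 without kidney monuron replicate 1, 2 or 3 or kidney control replicate 4, and the 1 hepatocyte marker that fell became 2 without kidney control replicate 4.

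In liver, leukocyte markers lay higher as a group in the arrays labelled monuron although 0 of 36 members passed over all genes (4 higher and 0 lower adjusted over the list alone). Their median was 0.29 against -0.07 for the other genes (camera adjusted p = 1.72e-08, and adjusted p = 0.5157 with an estimated correlation). Of 26 interferon-stimulated genes 2 rose and 0 fell, with the same counts adjusted over the list alone (median 0.27, camera adjusted p = 6.43e-05, and adjusted p = 0.6297 with an estimated correlation). The 2 became 0 without liver monuron replicate 1, 2 or 3 or liver control replicate 1, 2 or 4. In the 72 h cells 11 of 19 genes of iron and haem handling fell and 5 rose, with the same counts adjusted over the list alone, and the list did not pass (median -0.48, camera adjusted p = 0.1239, and adjusted p = 0.5157 with an estimated correlation). Slc11a2, an importer of iron, fell by 1.33 (SE 0.13, adjusted p = 5.70e-07), a call that was not made for the mean of its probe sets (adjusted p = 0.0560). Of 18 targets of p53 11 rose and 3 fell at 72 h, with the same counts adjusted over the list alone, and the list did not pass (median 0.43, camera adjusted p = 0.1310, and adjusted p = 0.6297 with an estimated correlation).

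Further lists were called by camera at the preset correlation, 0 of them with an estimated correlation, and most with few called members. In liver the lists called higher against the median of -0.07 for the other genes were endothelial markers (median 0.10, 1 of 19 called higher, adjusted p = 0.0118), fibroblast, stellate and smooth muscle markers (0.21, 0 of 16, 0.0183), extracellular matrix genes (0.09, 2 of 35, 0.0356), hepatocyte markers (0.04, 0 of 29, 0.0491), kidney injury markers (0.22, 2 of 23, 0.0018), chaperones of the endoplasmic reticulum (0.07, 1 of 24, 0.0166) and genes that differ between the sexes (0.11, 1 of 19, 0.0020). Acute phase genes were called higher relative to the other genes (0.14, adjusted p = 8.59e-04), although 0 of 24 members passed higher and the only 1 that passed, Vnn1, was lower (-1.35, adjusted p = 0.0228). Vnn1 was not called without liver monuron replicate 1 or liver control replicate 1 or 2 (0.0708, 0.0775 and 0.0682). In the endothelial, matrix, injury, chaperone and sex lists 0 members were called without liver monuron replicate 1 or 3 or liver control replicate 1 or 2. The 1 endothelial call also ended without liver monuron replicate 2, the chaperone call without liver monuron replicate 2 or 4 or liver control replicate 4, and the sex call without liver control replicate 4. The 2 injury markers became 0 without liver monuron replicate 2 or liver control replicate 4, and the 2 matrix genes 1 without liver monuron replicate 2 or 4 and 0 without liver control replicate 4. Without the filter the calls of the endothelial, hepatocyte and matrix lists ended (0.1648, 0.1914 and 0.0814), and with arrays centred on their medians that of hepatocyte markers (0.2264). Leaving out 1 liver array ended the fibroblast call for monuron replicate 3 or control replicate 2 or 3 (0.0640, 0.0599 and 0.0666) and the matrix call for monuron replicate 3 or 4 or control replicate 3 (0.0633, 0.0856 and 0.1239). It ended the chaperone call for monuron replicate 4 or control replicate 3 (0.2075 and 0.0994), the acute phase call for monuron replicate 4 (0.0902) and the hepatocyte call for monuron replicate 1 or 2 or control replicate 1, 3 or 4 (0.0591 to 0.1507).

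In kidney the lists of cholesterol synthesis, fatty acid synthesis, leukocyte markers and the respiratory chain were called higher (adjusted p = 0.0396, 0.0254, 0.0324 and 0.0396) and heat shock genes lower (0.0324). In the 6 h cells chaperones of the endoplasmic reticulum and matrix genes were called higher (0.0072 and 0.0254) and NRF2 targets, PPARalpha targets, immediate early genes and ribosomal proteins lower (0.0491, 0.0356, 0.0387 and 0.0315). In the 24 h cells ribosomal proteins (5.84e-07), matrix genes (0.0087), glutathione and glucuronosyl transferases (0.0288), fibroblast markers (0.0424) and chaperones (0.0470) were called higher and glycolysis and hypoxia genes lower (0.0440). At 72 h immediate early genes were called higher (0.0304) and replication genes lower (0.0315). Each of these calls ended in at least 1 alternative besides the estimated correlation and fry, apart from those of chaperones at 6 h and of ribosomal proteins and matrix genes at 24 h.

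Directions in the organs were compared beyond the genes called in both. Without those, 613 of 818 genes called in kidney (74.9%) had the same sign in liver, and 162 of 207 called in liver (78.3%) had the same sign in kidney, against 52.9% and 55.0% expected from the shares of each sign. Other splits of the same rats also gave high shares (highest others 77.5% and 79.5%, medians 61.0% and 64.1%). With the real split counted, 2 and 3 of 35 splits reached the real shares, so chance cannot be excluded at 0.05.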
